A study of Homo sapiens with 12 samples.

How the data were processed

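The table analysed held read counts per gene for 12 libraries of MD901 lymphoma cells in a 2 by 2 design, 3 libraries in each of the groups vehicle, HDAC3i, AZA and both. Per the labels' protocols, messenger RNA libraries were made with the QuantSeq 3' kit. The deposited counts are whole numbers that the authors made with featureCounts 2.0.0 on the GRCh38 genome with Ensembl annotation release 90, per the file headers, without normalization. Per the same headers, reads were assigned without regard to strand (setting 0), and reads with several alignments or overlapping several genes were counted in full for each. Copies of a gene family, pseudogenes and overlapping or antisense genes therefore share counts and cannot be told apart. The submitters' processing notes name bcl2fastq 2.17.1.14, FastQC 0.11.6, cutadapt 2.1, HISAT2 2.1.0 and Subread 2.0.0. No row lacked a gene, and gene symbols were found for 98.7% of the 58302 identifiers. Of these genes, 27.9% share exon bases with another gene in the Ensembl release 90 annotation used for counting.

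Library totals ran from 9514826 to 14933374 counts, and the counts outside the 4 abundant loci from 6864980 to 12655817. Counts were scaled with TMM factors and filtered with filterByExpr (minimum count 10), which left 16042 genes. One model with a mean per group was fitted to all 12 libraries in edgeR 4.0.16 (R 4.3.3) with the robust quasi-likelihood method, and 6 contrasts were tested, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. Levels are CPM, the counts scaled to a fixed library size with the TMM factors, computed here from the deposited counts. Standard errors of log2 changes were derived from the fitted change and its F statistic. A fold against a group at 0 counts is a lower bound against a floor of 3 counts per library, and such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

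The 28 gene lists were fixed before the data were examined. One of them, of erythroid genes, had no tested member, and 27 were tested in each contrast with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over 162 tests. Counts of list members are over those that passed the filter on low counts, which a rise in 1 group can bring about. Named genes followed a rule fixed at the same time. For each comparison against vehicle the rule took the 10 largest rises and falls among called genes with a mean log2 CPM of at least 1, no overlap between replicates and a symbol that is not a clone or LINC name, and 6 of each in the other contrasts, with overlap allowed for the interaction. It added up to 4 called members per list with the smallest p, and HDAC3 and DNMT1 in each comparison. Some genes that this rule names are not reported here. Chance gives no overlap in 10% of genes for 3 against 3 libraries.

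On simulated counts with known changes, the method recovered 56.8% of genes changed by 1 on the log2 scale and 88.7% of those changed by 2 in the HDAC3i comparison of 15426 genes, and 29.8% and 75% for the interaction of 15425 genes. Of the calls, 14 of 154 in the HDAC3i comparison and 8 of 111 for the interaction were of genes without a change. Alternatives fixed in advance were RLE factors, library totals alone, no filter and a stricter filter on low counts (CPM above 1 in 3 libraries), DESeq2 1.42.0, limma-voom, a replicate block, the compared groups alone, an added threshold of 1 on the log2 scale, and each library left out in turn. For the lists, camera with an estimated correlation and fry were also run.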

Results

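RNA was measured in MD901, an established human cell line of diffuse large B-cell lymphoma, after treatment with vehicle, an HDAC3 inhibitor (HDAC3i), 5-azacitidine (AZA) or both. HDAC3 is a histone deacetylase that acts in the NCOR and SMRT corepressor complexes, and 5-azacitidine is a nucleoside analog that traps DNA methyltransferases such as DNMT1. Each of the 4 groups had 3 libraries, made with a kit that reads the 3' ends of messenger RNAs. AZA was given daily at 200 nM from day 0 to day 4, HDAC3i at 10 µM on days 2 and 4, and the series analysed cells at day 5. Library totals ran from 9514826 to 14933374 counts over 58302 genes, of which 16042 passed the filter on low counts and were tested. Near-identical loci in the ribosomal DNA region of chromosome 21, 4 in number, held 47.3% of the counts of AZA replicate 1, against 13.7% to 27.8% in the other 11 libraries. Reads with several alignments were counted in full for each locus, and the 4 loci held near-equal mean shares, 5.51% to 5.61%. The same reads may therefore stand up to 4 times in these shares and in the library totals, so the shares need not hold for reads. AZA replicate 1 had a count for 19837 genes, and the other libraries for 22108 to 27820. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

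The series title places the question in whether an HDAC3 inhibitor acts more strongly together with 5-azacitidine. The transcripts of both drug targets did not pass the test in any comparison. HDAC3 (ENSG00000171720, chromosome 5, 141620876 to 141636870, GRCh38) was at 32.4 ± 3.88 CPM (SD, n = 3) with vehicle, 37.4 ± 2.42 with HDAC3i, 31.6 ± 2.86 with AZA and 30.8 ± 2.27 with both. DNMT1 (ENSG00000130816, chromosome 19, 10133345 to 10231286) was at 186 ± 43.4 CPM with vehicle and 143 ± 18.3 with AZA, a log2 difference of -0.38 ± 0.18 (SE) with an adjusted p of 0.189 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

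With HDAC3i alone CDKN1A, which encodes the cell cycle inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687339), rose 3.08-fold, from 16.2 ± 0.226 CPM to 49.9 ± 3.21 (SD, n = 3), a log2 change of 1.62 ± 0.12 (SE). CD48 rose from 10.0 ± 3.06 CPM to 44.3 ± 8.13, and the B-cell surface gene MS4A1, which encodes CD20, from 2.19 ± 0.313 to 7.53 ± 1.11. The sodium channel gene SCN3A rose 24.2-fold and the germ-cell gene TEX19 16.5-fold. SOHLH2 was at 0 counts with vehicle and at 17 counts in all with HDAC3i, at least 2.22-fold higher against a floor of 3 counts per library.

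The MHC class II list, which presents antigen to CD4 T cells, had 4 of 16 members higher with HDAC3i and none lower. These were HLA-DQB1, HLA-DQA1, HLA-DPB1 and HLA-DRA, which rose 2.35, 1.72, 1.70 and 1.62-fold. Adjusted over the list alone, 9 members were higher and 1 was lower. Of the MHC class I and peptide loading list, 5 of 19 members rose, among them HLA-E from 22.0 ± 2.17 CPM to 41.7 ± 2.17, with 8 higher adjusted over the list alone. Interferon-stimulated genes had 9 members higher and 1 lower of 42, or 14 and 1 adjusted over the list alone, with OAS3 and BST2 up 10.3 and 3.33-fold and IRF7 down to 0.621 ± 0.326 CPM from 2.14 ± 0.704. Of the B-cell and germinal-centre list 8 of 35 members rose, or 12 with 3 lower adjusted over the list alone. The plasma cell list had 3 of 24 higher (XBP1, CD38 and EDEM1), or 5 adjusted over the list alone, and the cholesterol synthesis list 2 of 28 (HMGCS1 and MVD), or 4. The integrated stress and unfolded protein response list had 5 of 27 higher, or 10 adjusted over the list alone, with CHAC1 up 2.38-fold. The camera test with Benjamini-Hochberg adjustment called these 7 lists, the p53 targets and the cytokine list as higher, and the MYC and ribosome biogenesis list as lower.

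With an estimated correlation, camera kept the plasma cell list (adjusted p = 0.0147) and the cholesterol list (adjusted p = 0.0272). The others then had an adjusted p of 0.151 for MHC class II, 0.138 for MHC class I, 0.183 for the interferon list, 0.0777 for the B-cell list, 0.112 for the stress response list, 0.157 for p53 targets, 0.112 for cytokines and 0.099 for the MYC list. Among the falls, ABHD12B went from 3.27 ± 0.419 CPM to 0.973 ± 0.293. CARD9 fell by 1.11 on the log2 scale and DNLZ fell by 1.10, and the pair share exon bases and so in part the same reads. In all, 293 genes were higher and 69 lower in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. Scaled by library totals alone the split was 135 higher and 4 lower. Without vehicle replicate 1, vehicle replicate 2 or HDAC3i replicate 1 the test called 169, 179 and 179 genes higher, and the count of lower genes was 29, 21 and 30 without vehicle replicates 1, 2 and 3 and 16 and 27 without HDAC3i replicates 1 and 2.

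Several calls with HDAC3i were lost in fits without 1 library. HLA-DQB1, HLA-E, CD38, HMGCS1 and CHAC1 were called in each fit without 1 library. Without vehicle replicate 1 the calls of HLA-DPB1, HLA-DQA1, HLA-DRA, XBP1, EDEM1, MVD and IRF7 were lost, and these were also lost without vehicle replicate 2. Leaving out HDAC3i replicate 1 ended those of HLA-DQA1, HLA-DRA, EDEM1 and MVD, HDAC3i replicate 2 those of EDEM1 and IRF7, HDAC3i replicate 3 those of HLA-DRA and IRF7, and vehicle replicate 3 those of EDEM1, MVD and IRF7. The highest adjusted p in these edgeR fits was 0.0679 for HLA-DPB1, 0.158 for HLA-DQA1, 0.215 for HLA-DRA, 0.0536 for XBP1, 0.149 for EDEM1, 0.194 for MVD and 0.155 for IRF7. With library totals alone the calls of these 7 genes and of HLA-E, CD38, HMGCS1 and CHAC1 were lost, and HLA-DQB1 was called. The p53 list lost its camera call in 8 of 12 fits without 1 library, with an adjusted p of up to 0.294.

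**Figure D1:**
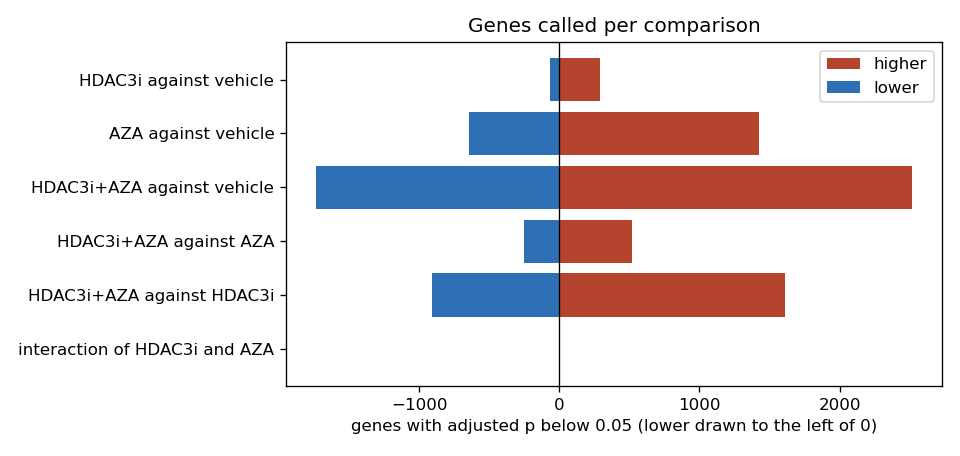
Bars give the number of genes past an adjusted p of 0.05 in each of the 6 comparisons, higher to the right and lower to the left of 0, each from 3 libraries per group. The combination against vehicle has the longest bars, with 2519 genes higher and 1740 lower.

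With AZA alone, genes of the cancer-testis class, which are normally expressed in germ cells, went from no or few counts to clear expression. PAGE5, CTAG2 and MAGEA4, of the cancer-testis and germline list, had 0 counts in every vehicle library. They stood at 31.9 ± 2.74, 23.6 ± 4.64 and 23.5 ± 1.77 CPM (SD, n = 3) with AZA, at least 161, 119 and 118-fold higher. Outside that list, PNMA5 (ENSG00000198883, chromosome X, 152988824 to 152994127) and VCX were likewise at 0 with vehicle. They were at 259 ± 37.7 and 43.5 ± 4.05 CPM with AZA, at least 1310 and 220-fold higher. The cancer-testis and germline list had 65 members, of which 46 passed the filter on low counts, and 42 of these rose and none fell, or 43 adjusted over the list alone. The 26 members at 0 in each vehicle library could pass that filter only through other groups, and all 26 rose, as did 160 of the 176 other tested genes at 0 with vehicle, so the filter in part sets the share. Without the filter 44 of the 65 rose. Of those rises 29 were among the 40 members at 0 in each vehicle library. Of the 29372 other genes at 0 with vehicle, those without a count in any library included, 294 rose (1%). Of the 20 tested members with a count in a vehicle library 16 rose. Members with few vehicle counts may also have passed the filter through other groups, so this share is not free of it. The median fitted log2 change of that list was 8.46, and 4.82 with the 26 members at 0 in each vehicle library set to their lower bounds. The camera call of this list also held with an estimated correlation (adjusted p = 7.26e-05, Benjamini-Hochberg), and then also without the genes at 0 in each vehicle library (adjusted p = 0.0129). The members left in that rerun had likewise passed the filter. SSX2 and SSX2B, at 67.2 ± 7.89 and 66.8 ± 8.00 CPM, are near-identical copies whose shared reads were counted for both, so their levels are uncertain.

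**Figure D2:**
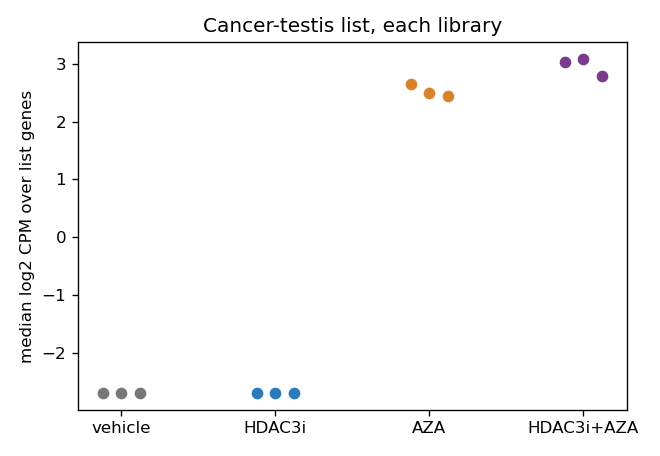
Each point is the median log2 CPM over the 46 tested genes of the cancer-testis and germline list in 1 library, by group on the horizontal axis. The 3 AZA libraries lie between 2.44 and 2.65 and the 3 combination libraries between 2.78 and 3.08, while each vehicle and HDAC3i library lies at -2.69, the level that a count of 0 takes on this scale.

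DNA replication genes fell with AZA. The S phase list had 13 of 47 members lower and none higher, or 19 adjusted over the list alone, with an adjusted p of 0.00243 in camera with an estimated correlation and Benjamini-Hochberg adjustment. CDC6, which loads the replicative helicase, went from 52.6 ± 2.09 CPM to 31.8 ± 1.26, and RFC3, a subunit of the clamp loader, from 317 ± 19.5 to 187 ± 28.1. The de novo DNA methyltransferase gene DNMT3B rose 2.08-fold, from 16.3 ± 2.43 CPM to 33.9 ± 6.16. The p53 targets MDM2 and BTG2 rose 2.20 and 3.61-fold, within a list that had 6 members higher and 2 lower of 32 and that camera did not call (adjusted p = 0.0762). Without the genes at 0 in each vehicle library camera called that list higher (adjusted p = 0.0386), though not with an estimated correlation (adjusted p = 0.135). DHRS2, a gene often raised by histone deacetylase inhibitors, rose 47.4-fold with AZA, from 0.773 ± 0.428 CPM to 36.6 ± 7.78, and stood at 0.544 ± 0.157 CPM with HDAC3i alone.

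LAT2, an adaptor of B-cell signalling, fell with AZA from 27.4 ± 2.49 CPM to 4.17 ± 0.929, and CD79A, a chain of the B-cell receptor, from 17.3 ± 1.69 to 5.92 ± 1.53. The B-cell and germinal-centre list went both ways, with 5 members higher and 9 lower of 35, and camera did not call it (adjusted p = 0.139). The integrated stress list had 10 higher and 1 lower of 27, or 12 and 2 adjusted over the list alone, and the cholesterol list 1 higher and 5 lower of 28. The camera calls of those lists, of the MYC list (2 of 37 lower) and of the G2 and mitosis list (2 of 44 lower) had an adjusted p of 0.333, 0.0687, 0.167 and 0.347 with an estimated correlation. Adjusted over the list alone, the MYC list had 1 member lower and the G2 and mitosis list 0. Of the lists for other lineages, the T- and NK-cell list had 4 of 8 tested members higher, with CD247 and CD4 at 1.34 ± 0.878 and 0.993 ± 0.53 CPM, the myeloid list 1 of 3 higher, and the epithelial and stromal list none higher and 1 lower of 9. These lists had 22, 20 and 21 members, of which the rest had too few counts to be tested. Camera called none of these (adjusted p = 0.112, 0.229 and 0.715). In all, 1422 genes were higher and 645 lower with AZA by edgeR's quasi-likelihood test, 1358 and 607 without AZA replicate 1, and 848 and 311 with library totals alone. Without vehicle replicate 3 or AZA replicate 3 the test called 392 and 423 genes lower, and library totals alone moved the median log2 change of all genes by -0.12, from 0.00824 to -0.114. The stress response list had an adjusted p of 0.0757 in camera without AZA replicate 2 and 0.105 with library totals alone.

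Of the cancer-testis list 45 of the 46 tested members rose with the combination against vehicle, also 45 adjusted over the list alone. All 26 tested members at 0 in each vehicle library rose, as did all 176 other tested genes at 0 with vehicle, so the filter in part sets the share. The list median was 8.65 on the log2 scale, or 5.51 with genes at 0 set to their bounds. Without the filter on low counts 49 of its 65 members rose and 1 fell. Of those rises 30 were among the 40 members at 0 in each vehicle library. Of the 29372 other genes at 0 with vehicle, those without a count in any library included, 549 rose (1.87%). Of the 20 tested members with a count in a vehicle library 19 rose. These too may have passed the filter through other groups. PNMA5, which is not on that list, was at 189 ± 7.44 CPM (SD, n = 3), at least 955-fold above vehicle. DHRS2 reached 104 ± 8.79 CPM, 135-fold above vehicle. The integrated stress and unfolded protein response list had 20 of 27 members higher and 1 lower, or 21 and 1 adjusted over the list alone. SLC7A11, a cystine transporter, rose 12.8-fold to 33.5 ± 3.33 CPM, CHAC1 11.5-fold, and the amino acid synthesis genes PSAT1 and ASNS 3.41 and 3.19-fold. The call of that list had an adjusted p of 0.106 with an estimated correlation.

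Of the MYC and ribosome biogenesis list, 18 of 37 members were lower with the combination, and 18 adjusted over the list alone. LDHA, lactate dehydrogenase A, fell from 692 ± 12.2 CPM to 326 ± 9.99, and EXOSC5, a subunit of the RNA exosome, fell by 1.03 on the log2 scale (SE 0.17). The S phase list had 14 of 47 lower, or 16 adjusted over the list alone, with PCNA going from 151 ± 14.9 CPM to 88.6 ± 8.28. Camera with an estimated correlation and Benjamini-Hochberg adjustment called the cancer-testis (adjusted p = 1.12e-04), S phase (adjusted p = 0.0112) and MYC lists (adjusted p = 0.0493). IGLL1, a surrogate light chain gene (ENSG00000128322, chromosome 22, 23573125 to 23580308), fell from 712 ± 180 CPM to 99.9 ± 5.13, and the glycine receptor gene GLRB from 2.83 ± 0.784 to 0.0852 ± 0.0819. Within the MHC class I list HLA-F rose while the proteasome genes PSMB10 and PSME2 fell, with 5 members higher and 4 lower of 19, a median log2 change of -0.15 and a mean of 0.07.

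With the combination the T- and NK-cell list had 5 of 8 tested members higher (of 22 in all), the myeloid list 2 of 3 (of 20) and the epithelial and stromal list 4 of 9 (of 21), with KRT18 at 2.17 ± 0.677 CPM and CD247 at 3.29 ± 0.366, while VIM fell from 218 ± 4.39 CPM to 112 ± 3.68. Camera did not call the myeloid (adjusted p = 0.167) or the epithelial and stromal list (adjusted p = 0.0778). The 4 abundant chromosome 21 loci held 23.7% to 27.8% of the counts of the combination libraries and 15.3% to 19.4% with vehicle. Camera also called the interferon list (11 of 42 higher), the plasma cell list (11 of 24), the cytokine list (4 of 9 tested, of 32), the genes commonly raised by HDAC inhibitors (9 of 18) and the T- and NK-cell list. With an estimated correlation their adjusted p was 0.424, 0.121, 0.106, 0.0989 and 0.121. The T- and NK-cell list was not called without the genes at 0 in each vehicle library (adjusted p = 0.0643). The interferon call was lost without vehicle replicate 2 or combination replicate 1, with an adjusted p of up to 0.075, and the plasma cell call in 7 of 12 fits without 1 library, with an adjusted p of up to 0.0672. In all, 2519 genes were higher and 1740 lower, a share of 59.1% higher, in edgeR's quasi-likelihood test. Scaled by library totals alone, 1677 were higher and 585 lower.

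Adding HDAC3i to AZA raised PMEL, TEX19 and IL21R from low levels. PMEL, a melanosome gene (ENSG00000185664, chromosome 12, 55954105 to 55973317), went from 0.289 ± 0.198 CPM with AZA to 7.05 ± 0.906 with both (SD, n = 3), TEX19 from 3.39 ± 0.292 to 41.2 ± 1.07, and the cytokine receptor gene IL21R from 0.734 ± 0.449 to 8.87 ± 0.628. CDKN1A rose 2.29-fold and CD48 6.35-fold. Of the cancer-testis list 6 of 46 members were higher and 2 lower, with PRAME rising from 2.52 ± 0.547 CPM to 12.8 ± 1.39 and DAZL falling from 10.4 ± 1.27 to 3.93 ± 0.297, a fall not called with library totals alone (adjusted p = 0.0537). The stress response list had 13 of 27 higher, or 18 adjusted over the list alone, and the interferon list 8 of 42, or 13. The MYC list had 3 of 37 lower, or 11 adjusted over the list alone. None of the 8 lists that camera called here was called with an estimated correlation, where the stress response, MYC and cytokine lists each had an adjusted p of 0.0687 and the interferon list 0.273. The plasma cell list had 0.0892, the genes commonly raised by HDAC inhibitors 0.0777, the G2 and mitosis list 0.229 and the epithelial and stromal list 0.227, and the last lost its call also without AZA replicate 1 (adjusted p = 0.0513).

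Of the 293 genes higher with HDAC3i alone, 164 were also higher with both agents than with AZA, where independent lists of these sizes would share 9.41. In all, 515 genes were higher and 250 lower than with AZA in edgeR's quasi-likelihood test. Library totals alone gave 325 higher and 21 lower, and put the median log2 change of the genes at 0.11, against -0.00539. The count of lower genes was 121 without AZA replicate 1, 128 without AZA replicate 2, and 160, 85 and 79 without combination replicates 1, 2 and 3, and the count of higher genes was 304 without AZA replicate 2 and 342, 290 and 294 without those combination replicates.

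When AZA was added to HDAC3i, 42 of 46 tested members of the cancer-testis list were higher, and 20 of the 24 with a count in an HDAC3i library. Those 24 may also have passed the filter on low counts through other groups. Without the filter 45 of the 65 members were higher and 1 was lower. GLRB fell from 3.95 ± 0.544 CPM with HDAC3i to 0.0852 ± 0.0819 with both (SD, n = 3), LAT2 from 45.3 ± 5.32 to 7.98 ± 1.36, and the glycogen branching enzyme gene GBE1 from 62.4 ± 5.93 to 10.5 ± 1.26. The B-cell and germinal-centre list had 6 members higher and 15 lower of 35, or 8 and 16 adjusted over the list alone, with CD79A at 25.5 ± 3.08 CPM with HDAC3i and 9.37 ± 1.94 with both. Of the MHC class I list 7 of 19 were lower, all of the 4 examples named by the rule (PSMB8, PSMB9, PSMB10 and PSME2) being proteasome genes. The cholesterol list had 10 of 28 lower and 1 higher, or 15 and 2 adjusted over the list alone, with HMGCS1 going from 98.3 ± 0.311 CPM to 50.4 ± 1.36. With an estimated correlation, camera and Benjamini-Hochberg adjustment gave an adjusted p of 0.0147 for the cholesterol list, 0.00729 for the S phase list, 7.26e-05 for the cancer-testis list, 0.157 for MHC class I and 0.143 for the B-cell list. The other camera calls were the MYC list (9 of 37 lower), the stress response list (15 higher and 3 lower of 27), the glycolysis and hypoxia list (4 higher and 8 lower of 29), the T- and NK-cell list (4 of 8 higher) and the myeloid list (1 of 3). Their adjusted p with an estimated correlation was 0.112, 0.167, 0.121, 0.112 and 0.151, the T- and NK-cell list was not called without the genes at 0 in each HDAC3i library (adjusted p = 0.131), and the glycolysis list had a median log2 change of -0.29 and a mean of 0.12. In all, 1611 genes were higher and 908 lower, and 1082 and 230 with library totals alone. Without combination replicates 2 and 3 the count of lower genes was 604 and 510.

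The interaction asks whether the combination differed from the sum of the single-agent changes on the log2 scale. The test called 5 genes, all below additive, and none above. SMAD1, a transducer of BMP signalling (chromosome 4, 145481194 to 145558079), had an interaction of -1.30 ± 0.18 (SE), an adjusted p of 0.011 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It stood at 17.3 ± 1.10 CPM with vehicle, 45.2 ± 3.33 with HDAC3i, 44.7 ± 1.75 with AZA and 47.2 ± 3.71 with both (SD, n = 3). THSD7A stood at 7.61 ± 0.901, 30.2 ± 2.16, 17.9 ± 5.10 and 20.7 ± 2.25 CPM in the same order. GBE1 and the protocadherin gene PCDH9 rose with HDAC3i alone, and were at 10.5 ± 1.26 and 12.6 ± 0.221 CPM with both agents. The count of 0 genes above additive stood beside 754 genes at an unadjusted p below 0.05 in either direction, where 802 would pass with no change, and DESeq2 called 3 above and 14 below. The count of genes below additive was 3 without vehicle replicate 1, 0 without vehicle replicate 2, 2 without AZA replicate 3, and 2 and 0 without combination replicates 1 and 2. Library totals alone called 0 genes, and limma-voom 0 above and 4 below.

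Camera called 7 lists for the interaction, with MHC class II, MHC class I, B-cell, p53 and cholesterol genes below additive and G2 and mitosis and stress response genes above. No member of the MHC class II, MHC class I, p53, cholesterol, G2 and mitosis or stress response lists passed the test for single genes. With an estimated correlation none of the 7 was called, and the adjusted p was 0.225, 0.162, 0.157, 0.112, 0.121, 0.121 and 0.273 in that order. The B-cell list lost its call without vehicle replicate 3, HDAC3i replicate 2 or AZA replicate 2, the p53 list without HDAC3i replicate 2, and the stress response list without combination replicate 1, with an adjusted p of up to 0.0897, 0.0761 and 0.0602. The cholesterol list lost it in 4 fits, without vehicle replicate 3, HDAC3i replicate 1, AZA replicate 3 or combination replicate 2, with an adjusted p of up to 0.117.

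The responses to the single agents had a correlation of 0.23 across the 16042 genes, which are not independent replicates, and a covariance of 0.159. In 20 simulations without any change, all libraries were drawn from the vehicle means, and both comparisons used the same simulated vehicle libraries. These gave a mean correlation of 0.467 and a mean covariance of 0.0937. Real changes add to the spread of the observed values, so the observed correlation cannot be read against the simulated one. Genes higher with both agents numbered 85, where independent lists would share 26.0, and 10 were lower with both, against 2.77 for independent lists. The simulations shared at most 1 higher gene. They held no changed genes, so this cannot show how much overlap shared controls give among real calls. Another 38 genes went in opposite directions, 36 higher with HDAC3i and lower with AZA, where independent lists would share 11.8, and 2 the other way, against 6.12. Among the 36 were TLR10 and CHI3L2, each higher with HDAC3i and lower with AZA, though the AZA call of TLR10 was lost without AZA replicate 3 (adjusted p = 0.0536). With 3 vehicle libraries the controls could not be split into parts of at least 2 libraries. Part of the excess of genes called in the same direction may therefore come from the shared controls. Noise in shared controls moves both changes the same way, so it would not account for the 36 genes called in opposite directions.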

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

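The tests of a wrong label and the count with near-identical genes taken once were chosen after the data were seen. The interaction test called 5 genes, of which those reported here had log2 values of -1.47 for GBE1, -1.30 for SMAD1, -1.78 for THSD7A and -1.35 for PCDH9.

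Of the 85 genes higher with both single agents, 79 had an interaction below 0, with a median of -0.638. These were chosen on the same libraries, so selection on noise in the shared vehicle libraries may account for much of it. Genes were also chosen on the libraries of 1 replicate number, by a log2 rise above 1 with each single agent and no test. The interaction was measured on the other 8 libraries. For the 83, 84 and 83 genes chosen, the medians were 0.0147, -0.245 and 0.0165, so the highest was not below 0. Their median HDAC3i change on the held-out libraries was 0.705, 0.821 and 0.781. These sets were not the 85 called genes, so the medians do not decide what accounts for the values of those 85. A response near a ceiling, as for SMAD1, stays open and was not tested.

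AZA replicate 1 lay farther from its group than any other library, at a root mean square distance of 0.714 in log2 CPM. Fewer counts for other genes could not be the whole cause, since after thinning each library to 6864980 counts outside the abundant loci its mean distance was 0.664 and the next largest, HDAC3i replicate 3, was at 0.621. The thinning narrowed the gap, so depth may carry part of it. A vehicle or HDAC3i library under a wrong label is argued against by the cancer-testis list. Its median was 2.65 log2 CPM in this library, near the 2.47 of the other AZA libraries. A combination library is argued against by the genes higher with both agents than with AZA in the fit without this library. Of these 367 genes, 365 were also tested in the main fit. Their median was 2.45 log2 CPM in AZA replicate 1, 2.26 in the other AZA libraries and 3.61 in the combination. What made the ribosomal loci take more of its counts was not tested, and no biological explanation was tested.

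For the cancer-testis rises with AZA, 3 technical explanations were tested. Counting near-identical members once left 39 of the 42 called members, library totals alone called 41, and leaving out AZA replicate 1 called 43. Scaling, that library and reads shared between near-identical members are therefore unlikely to be the whole cause. Members that share only part of their reads were not merged, so partial sharing within gene families was not tested. A response to AZA is a hypothesis that these data leave standing.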

How the results depend on the processing

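Alternatives that removed the abundant loci, counted near-identical genes once, left out a pair of libraries, or ran camera without genes at 0 in the reference group were chosen after seeing the data. No called gene changed direction among the named ones. Of 438 calls of named genes, 270 held in each alternative fixed in advance that was run for named genes and tested the gene. In each fit without 1 library 321 held. The compared groups alone and the threshold of 1 on the log2 scale were not run for named genes. Of 50 list calls, 10 held in each alternative fixed in advance that was run for lists, and 41 in each fit without 1 library. Lists were not run with the other filters, DESeq2, limma-voom, the compared groups alone or that threshold.

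In the order of the report's comparisons, library totals alone gave 135 higher and 4 lower for HDAC3i, 848 and 311 for AZA, 1677 and 585 for the combination, 325 and 21 against AZA, 230 lower against HDAC3i and 0 below additive, with a median log2 change of all genes of -0.114 for AZA against vehicle, 0.11 against AZA and 0.102 for the interaction, shifts of -0.122, 0.115 and 0.12. Without a filter, lower genes numbered 118, 1078, 413 and 1407 for HDAC3i, AZA, and the combination against AZA and against HDAC3i, and the interaction called 8 above and 17 below additive. DESeq2 called 114 genes lower with HDAC3i and 3 and 14 for the interaction. Fitting the compared groups alone called 28 lower with HDAC3i. A log2 change above 1 left 12, 131, 235, 45 and 159 lower genes. The causes were not tested.

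Leaving out HDAC3i replicate 3 and AZA replicate 1 together called 136 lower with HDAC3i, and 13 above and 9 below additive. That pair was picked by hand before distances were measured; it is the farthest pair by distance but not by correlation, so no result rests on it.

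Without 1 library in turn, higher and lower genes ranged over 169 to 294 and 16 to 87 for HDAC3i, 1100 to 1358 and 392 to 607 for AZA, 2086 to 2214 and 1183 to 1452 for the combination, 290 to 406 and 79 to 342 against AZA, 1309 to 1531 and 510 to 941 against HDAC3i, and 0 to 6 below additive. Called lists ranged over 9 to 12, 5 to 8, 8 to 12, 7 to 10, 10 to 12 and 6 to 9, and the correlation of the single-agent responses over 0.164 to 0.343. That correlation was 0.114 over genes called with either agent.

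With an estimated correlation camera called 2, 2, 3, 0, 3 and 0 lists, where the preset one called 10, 6, 9, 8, 10 and 7. Fry, which asks another question, called 12 for AZA, 16 for the combination, 13 against AZA, 18 against HDAC3i and 4 for the interaction.

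With a replicate block 44 genes were lower with HDAC3i (69 without it). Of same-numbered pairs of libraries 4 of 18 had a correlation above 0.1 (all 18 from -0.359 to 0.416), and 3 of 12 libraries correlated best with their own number. Vehicle and HDAC3i replicates 2 had 0.368 and replicates 3 had 0.416, and the crossed pairs -0.388 and -0.394. All of these correlations are of deviations of libraries from their group mean, and the deviations within a group are tied to one another. The crossed values therefore follow in part from the others and are not separate evidence.

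Each pair of groups makes 10 splits, too few for a share under 0.05. Only 1 split, the real one, called as many genes, at 262, 1650, 4617, 742 and 2184 with the compared groups alone, and the highest other split called 0. Each other split mixed libraries of both groups, so real differences entered its spread and few calls were to be had. These splits therefore do not decide whether the calls arose by chance. For the interaction 2 of 100 splits called at least 5 genes, the real one included. The other called 634, which points to a structure of the samples, since a regrouping can turn main effects into an interaction. The regroupings also mixed the groups, so main effects can enter their spread, and 2 of 100 is not a share under chance alone.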

Other observations

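The test of X-linked genes was chosen after the result was seen. Of the genes commonly raised by HDAC inhibitors, 3 of 18 tested members (of 28) were higher with HDAC3i (CDKN1A, MT2A and SYT11), and camera did not call the list (adjusted p = 0.197). The HDAC3i calls of MT2A and SYT11 were lost without vehicle replicate 1, vehicle replicate 2 or HDAC3i replicate 1, that of MT2A also without HDAC3i replicate 3 and that of SYT11 without vehicle replicate 3, with an adjusted p of up to 0.182 and 0.0738 in edgeR. AZA raised 5 members and lowered 1, TXNIP going from 37.3 ± 1.08 CPM to 83.5 ± 11.3 (SD, n = 3), and the combination raised 9 and lowered 1, with the metallothionein gene MT2A at 39.4 ± 15.1 CPM with vehicle and 128 ± 12.9 with both. Of the cytokine list of 32 members 9 were tested, and 4 were higher with the combination (camera, adjusted p = 0.011), and the adjusted p was 0.106 with an estimated correlation. IL32 rose to 8.67 ± 1.46 CPM from 0.412 ± 0.393 and IL23A to 5.86 ± 0.766 from 0.471 ± 0.254.

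Of the pro-apoptotic BCL2 family 3 of 9 members were higher and 3 lower with the combination, a list that camera did not call (adjusted p = 0.735). HRK rose from 10.8 ± 0.46 CPM to 20.5 ± 0.921 and PMAIP1 from 41.9 ± 4.13 to 77.4 ± 13.5, while BIK went from 43.1 ± 5.91 to 23.7 ± 0.607 (SD, n = 3). Of the glycolysis and hypoxia list 5 of 29 were higher and 10 lower, with TPI1 going from 250.4 ± 32.4 CPM to 142 ± 14.6, and camera did not call it (adjusted p = 0.0652).

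Genes higher with AZA lay often on the X chromosome. Of the 1422 higher genes 126 were X-linked, 8.86% against 3.39% of the other tested genes (Fisher's exact test, odds ratio 2.77, p = 2.71e-19, with genes treated as independent, which they are not). Genes near 0 with vehicle pass the filter on low counts through other groups, so the filter may in part set these values. Among genes with a vehicle mean of at least 3 counts the odds ratio was 0.844 (Fisher's exact test, p = 0.454, 27 of 936 higher genes X-linked). The excess may therefore belong to genes that were silent with vehicle, such as PNMA5, VCX and MAGEA4, and was not seen among X-linked genes in general.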
